A study of Rattus norvegicus with 9 samples.

How the data were processed

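Small RNA of exosomes, the small membrane vesicles that cells release, was sequenced on the BGISEQ-500 platform from rat primary peritoneal macrophages, which were taken from untreated rat by lavage. There were 9 libraries in 3 groups of 3. Control cultures received 0.1% DMSO for 24 h, LPS cultures received lipopolysaccharide at 100 ng/ml for 6 h, and LPS+AS-IV cultures received astragaloside IV, a saponin of Astragalus root, at 150 µM for 24 h before LPS. DMSO is listed for Control alone, so vehicle cannot be told apart from treatment in comparisons with Control. LPS cultures have no listed vehicle for the 24 h of astragaloside IV. RNA was extracted with a commercial exosome RNA and protein isolation kit, per the labels' protocols. The labels do not state that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

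The deposited table of the whole series held whole-number read counts for 201 mature rat miRNAs, per the file headers, with no normalization. A further deposited column per library, headed exp, held whole-number counts that were never above the reads of the same miRNA. How the authors made it is not given in the sources used here, and it entered only an alternative. The deposited files of single libraries held the count of each distinct tag sequence of 15 to 45 nt, with 1 assignment to a mature miRNA, a miRNA hairpin, a piRNA or an Rfam family. The same files gave a score, per the file headers, which was the number of mismatches for miRNA and piRNA tags and a score for Rfam families. Tags counted here as having 1 mismatch were those assigned to a miRNA hairpin, all with a score of 1. No reference miRNA sequences were used here, so whether they differ in a base or only in length was not checked. Bowtie2 and the rat genome build Rnor_6.0 are named by the submitters' processing notes, without a role or a version. The miRBase release, the Rfam search tool and the adapter trimming are not given in the sources used here. No genome of that build was used here, so no coordinates are given. The table equalled the sum of the mature tags with 0 mismatches, except for 3 names in each of Control 1 and Control 3. Of 566 mature tag sequences, 21 had different assignments in different libraries, and 12 of those had at least 100 reads. Some of the 12 switched between miRNA names. Others were given to a miRNA in some libraries and to a piRNA or an Rfam family, outside the miRNA table, in others.

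Assigned reads per library were 7223406, 5449156 and 8215970 in Control, 9305041, 3484099 and 8936275 in LPS and 9527483, 9098417 and 6699947 in LPS+AS-IV. Reads in the miRNA table were far fewer, from 15426 in LPS+AS-IV 1 to 546599 in LPS+AS-IV 3. A count of 0 allowed up to 3 reads, which was between 5.99 CPM (reads scaled to a common library size with the TMM factors) in LPS+AS-IV 3 and 216 CPM in LPS+AS-IV 1. Shares of single libraries have 95% Wilson intervals. Reads made by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

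The comparisons were LPS against Control, LPS+AS-IV against LPS and LPS+AS-IV against Control. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the table's read counts, with TMM factors, filterByExpr defaults, 1 fit over the 9 libraries with group as the term, and a Benjamini-Hochberg adjusted p under 0.05. It covered 94 miRNAs. The other 107 fell under the filter, and 50 of the 94 were absent from at least 1 library. The square root of the common dispersion was 1.42. CPM values are scaled with the TMM factors. Compared with TMM, DESeq2 size factors moved the median log2 fold change of the tested miRNAs by -0.10 in LPS+AS-IV against LPS, and library totals moved it by -0.19 in LPS+AS-IV against Control. A fold against a group with 0 reads in its 3 libraries was computed against the mean of the floors of 3 reads per library. Each SE of an edgeR log2 fold change is its absolute value divided by the square root of the test's F statistic. Where a group had 0 reads in its 3 libraries, neither the fitted change nor this SE measures precision.

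The miRNAs named were chosen by a rule. It took the family of miR-204 and miR-211, up to 10 per direction past the threshold, the 5 with the smallest unadjusted p where fewer than 5 passed, the 10 most abundant in Control, and up to 4 members of each list and comparison. This gave 54 miRNAs. Of the 17 lists fixed, 10 had at least 3 tested members. These were LPS-induced in macrophages, inflammation-restraining, myeloid-enriched, pro-fibrotic, anti-fibrotic, let-7 family, miR-17-92 and paralogs, mesenchymal and smooth muscle, lymphocyte, and neural and endocrine. The others were the miR-204 and miR-211, miR-30, epithelial and mesothelial, endothelial, erythroid, striated muscle, and liver and serum lists. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 30 list tests. Class shares were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1. Groups, comparisons, main tests, lists, the naming rule and a first set of other settings were fixed before the data were examined.

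The first set of other settings held other scalings, DESeq2 1.42.0, no filter, at least 50 reads in 3 libraries, only the 6 libraries compared, replicate number as a block, each replicate left out, and the 3 most abundant miRNAs left out. Lists were also tested with an estimated correlation, with fry, and with no miRNA in more than 1 list. Settings chosen after the data were seen gave each tag sequence to 1 miRNA in every library, summed tags with 0 or 1 mismatch (both also for the lists), used the exp column, divided reads by the modal tag count, or left out 2 libraries. The mismatch sums also gave each tag to 1 miRNA in every library, so that setting does not separate mismatches from naming. The modal tag count is the centre of the fullest bin of reads per tag, over tags of at least 8 reads. Bins were 0.25 wide on a log2 scale, so it is not the most frequent single count. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.

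The test was checked on 20 simulated sets drawn from mean levels over the 9 libraries and the depth of each library. In each set 24 of 94 miRNAs were changed in LPS, and the test compared LPS against Control. At the estimated dispersion it recovered 7.92% of 4-fold and 35.4% of 16-fold changes, with 0.05 false calls per set. At a dispersion 0.1 times as large it recovered 69.6% and 96.2%, with 0.85 false calls per set. In the same comparison, camera gave an unadjusted p under 0.05 for a list of 9 miRNAs, all shifted 16-fold upward, in 20 of 20 sets. It did so for an unshifted list in 0 of 20. The real lists were judged by an adjusted p over 30 tests and some were smaller, so these counts do not give their power.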

Results

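Small RNA was measured in exosomes of rat peritoneal macrophages that received vehicle (Control), LPS, or astragaloside IV followed by LPS (LPS+AS-IV), with 3 libraries per group. The series title names miR-204-5p, Foxc1 and peritoneal fibrosis, so the comparisons ask how LPS alters exosomal miRNAs and whether astragaloside IV counters this. Mature miRNA reads in the table were 42178, 30861 and 75528 in Control, 25483, 65715 and 61579 in LPS, and 15426, 68845 and 546599 in LPS+AS-IV. The number of miRNAs detected was 111 ± 9.61 in Control, 99.3 ± 5.51 in LPS and 102 ± 1 in LPS+AS-IV (SD, n = 3 each). No replicate pair held identical values, and chi-square over its degrees of freedom was at least 30.5 in every replicate pair.

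Most assigned reads came from tRNA and rRNA. tRNA held 48.6% ± 12.9 of assigned reads in Control, 34.3% ± 24.1 in LPS and 34.8% ± 21.8 in LPS+AS-IV (SD, n = 3 each). rRNA held 40.9% ± 11.8, 41.3% ± 11.7 and 45.3% ± 6.79 in the same order. Mature miRNA held 0.690% ± 0.199, 0.95% ± 0.837 and 3.03% ± 4.45, and its share in LPS+AS-IV 3 was 8.16% (95% Wilson interval 8.14 to 8.18). piRNA held 2.70% ± 0.801, 16.3% ± 23.5 and 6.09% ± 2.23. The piRNA share of LPS 3 was 43.5% (95% Wilson interval 43.46 to 43.53), and rno_piR_001199 gave 3103173 reads there, 79.8% of that library's piRNA reads. The piRNA share was higher in each LPS+AS-IV library than in each Control library (exact permutation p = 0.1, the smallest this design can give, adjusted p = 1). All 18 comparisons of class shares had an adjusted p of 1 by exact permutation tests. Tags of 33 to 38 nt held 61.0% ± 12.03, 61.8% ± 11.4 and 50.3% ± 23.7 of assigned reads, and tags of 20 to 24 nt held 8.81% ± 7.35, 6.31% ± 2.02 and 17.6% ± 14.3 (SD, n = 3 each).

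**Figure D1:**
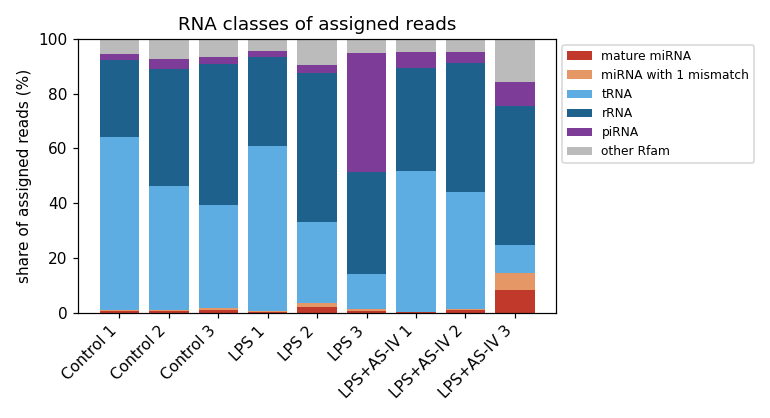
Share of assigned reads (%, vertical axis) in 6 RNA classes, stacked for each of the 9 libraries (horizontal axis). LPS 3 stands out by its piRNA share of 43.5% and LPS+AS-IV 3 by its mature miRNA share of 8.16%.

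In bins that double in width, the number of distinct tags did not fall off steadily with reads per tag. Each library had a second peak well above 1 read. Such bins cover more counts as they widen, so the peak belongs to the log scale and shows no excess at a single count. The modal count on this scale was 35, 35 and 70 reads in Control, 59, 70 and 140 in LPS, and 99, 49 and 664 in LPS+AS-IV. In units of this count, the mature miRNA reads came to 1205, 882 and 1079 in Control, 432, 939 and 440 in LPS, and 156, 1405 and 823 in LPS+AS-IV.

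**Figure D2:**
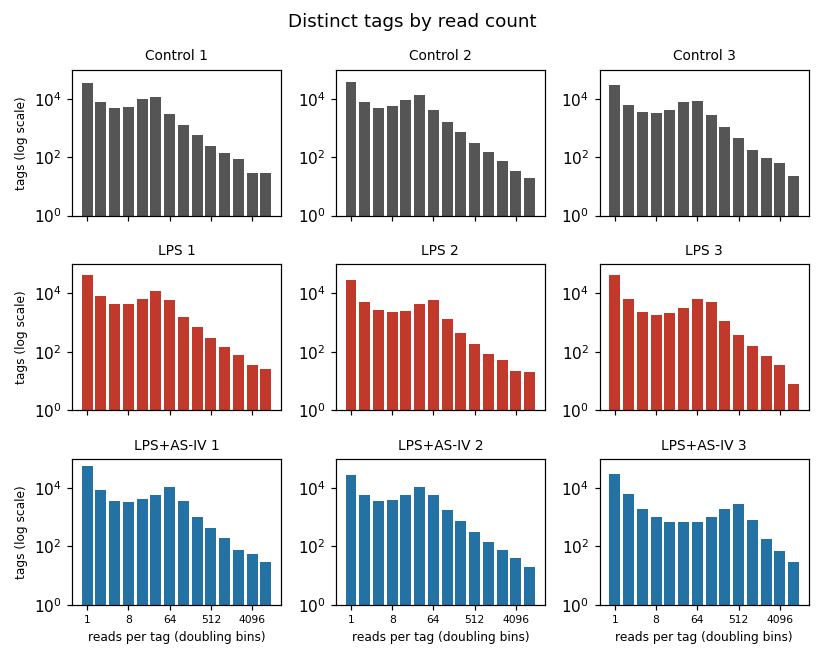
Number of distinct tags (vertical log axis starting at 1 tag) by reads per tag (horizontal axis, bins that double in width) in each of the 9 libraries, coloured by group. In these widening bins a second peak is visible in every panel, near a modal count between 35 and 664 reads.

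miR-181a-5p, which is abundant in lymphoid cells, was first in Control, with 10.7% ± 1.29 of the reads in the miRNA table (SD, n = 3). miR-423-3p held 8.54% ± 0.525, let-7b-5p 7.81% ± 0.701 and miR-92a-3p 7.72% ± 0.527 (SD, n = 3 each). miR-191a-5p, let-7i-5p, miR-26a-5p, the erythroid miR-451-5p and the lymphocyte miR-150-5p held between 3.29% and 4.23% each. The name miR-3596a held 8.30% ± 1.30 in Control (SD, n = 3), but most of these reads came from a tag that was named let-7a-5p in the other groups, as described for LPS against Control. The 10 miRNAs most abundant in Control held between 44.0% and 65.5% of the table's reads across the 9 libraries, miR-3596a included and let-7a-5p left out. With each tag given to 1 miRNA, let-7a-5p took the place of miR-3596a and the range was 53.4% to 68.9%. Of the LPS-responsive miRNAs, miR-146a-5p stood at 27353 ± 11989 CPM in Control, 20601 ± 7331 CPM in LPS and 34718 ± 29518 CPM in LPS+AS-IV (SD, n = 3 each).

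miR-204-5p, the miRNA named in the series title, had its lowest levels in the LPS group. It stood at 1360 ± 444 CPM in Control, 149 ± 156 CPM in LPS and 1862 ± 534 CPM in LPS+AS-IV (SD, n = 3 each). Every LPS library lay below every library of the other groups. The reads behind these values were few, 75, 54 and 63 in Control, 3, 1 and 20 in LPS, and 25, 159 and 681 in LPS+AS-IV. The tag TTCCCTTTGTCATCCTATGCCT gave most of them in every library but LPS+AS-IV 1 and LPS+AS-IV 3, where it gave 7 and 279 and the tag TTCCCTTTGTCATCCTATGCCTG gave 18 and 401. The log2 fold change was -3.18 (SE 1.96) in LPS against Control, 3.63 (SE 1.997) in LPS+AS-IV against LPS and 0.45 (SE 1.80) in LPS+AS-IV against Control. By edgeR's quasi-likelihood test the unadjusted p was 0.128, 0.0911 and 0.804, and the Benjamini-Hochberg adjusted p was 0.802, 0.963 and 0.981, so none passed. Its relative miR-211-5p had 17 reads in Control 2, 1 read in LPS+AS-IV 2 and none elsewhere, and was too low to test.

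**Figure D3:**
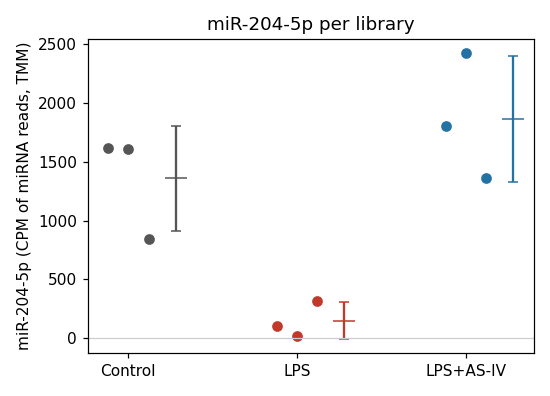
miR-204-5p in CPM of miRNA reads (vertical axis, TMM-scaled) for the 3 libraries of each group (horizontal axis), with the group mean and SD as a dash and bar to the right of the points. The LPS libraries, with a mean of 149 CPM, lie below all Control and LPS+AS-IV libraries.

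LPS against Control asks what LPS stimulation did to exosomal miRNAs, though DMSO is listed for Control alone and so differs along with LPS. The name let-7a-5p, a member of the abundant let-7 family, had 0 reads in the 3 Control libraries and 72710 ± 4292 CPM in LPS (SD, n = 3), at least 1120-fold higher. The name miR-3596a was the mirror image, with 79063 ± 15061 CPM in Control and 2236 ± 2324 CPM in LPS (SD, n = 3 each). The tag TGAGGTAGTAGGTTGTATAGTT was given to miR-3596a in the Control libraries and to let-7a-5p in the 6 others. The 271 reads of miR-3596a in LPS 2 and 129 in LPS 3 came from another tag, TGAGGTAGTAGGTTGTATAGTTG. It is the former tag with 1 base added, and it was named let-7a-5p in LPS 1, LPS+AS-IV 1 and LPS+AS-IV 2. With each tag given to 1 miRNA in every library, let-7a-5p stood at 77932 ± 12573 CPM in Control and 71459 ± 5492 CPM in LPS (SD, n = 3 each), and its log2 fold change was -0.13 (SE 0.26, edgeR adjusted p = 0.961).

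Other miRNAs differed in level without passing the test. miR-126a-3p, the endothelial miRNA, stood at 10618 ± 3249 CPM in Control and 3408 ± 1869 CPM in LPS (SD, n = 3 each). miR-127-3p, from the imprinted Dlk1-Dio3 cluster, stood at 9254 ± 2370 CPM and 1411 ± 265 CPM (SD, n = 3 each). miR-128-3p, miR-125a-5p and miR-181c-5p had no reads in LPS and were at least 13.3-fold, 18-fold and 10.4-fold lower than in Control against the floor. The bound was 9.29-fold for miR-125a-5p without Control 2 and 3.77-fold for miR-181c-5p without Control 1. With tags of 0 or 1 mismatch summed, a setting chosen after the data were seen, the log2 fold change of miR-125a-5p turned to 0.51 (SE 1.10), that of miR-128-3p was -3.96 (SE 2.70) and that of miR-181c-5p -9.16 (SE 3.84). miR-30b-5p had 0, 0 and 1 reads in Control and 16, 49 and 99 in LPS. The liver miRNA miR-122-5p stood at 2041 ± 1037 CPM in Control and 6033 ± 2641 CPM in LPS (SD, n = 3 each). miR-155-5p, which LPS is known to induce in macrophages, had 0, 26 and 0 reads in Control and 227, 2 and 234 in LPS. With 0 or 1 mismatch the fitted log2 fold change was smaller than in the deposited table for miR-30b-5p, 2.13 (SE 2.54) beside 7.24, and for miR-155-5p, 1.49 (SE 1.44) beside 3.96.

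Of 94 miRNAs, edgeR's quasi-likelihood test called 1 higher, let-7a-5p (log2 fold change 15.80, SE 0.56, adjusted p = 3.96e-10), and 0 lower in LPS. With 0 reads of let-7a-5p in Control, the fitted change and its SE give no precise size. At an unadjusted p under 0.05 there were 2 higher and 4 lower, and DESeq2 called 3, adding miR-3596a and miR-128-3p. With each tag given to 1 miRNA the count was 0 by edgeR, with 4 at an unadjusted p under 0.05. The edgeR count was 3 without Control 1, which added miR-3596a and miR-652-3p, and 2 without LPS 1, which added miR-3596a. A tag named miR-652-3p in Control 1 was named a piRNA in Control 2 (198 reads) and Control 3 (349 reads). With each tag given to 1 miRNA over all libraries, the log2 fold change of miR-652-3p was 0.72 (SE 0.65, edgeR adjusted p = 0.961).

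Among the lists, the 5 tested mesenchymal and smooth muscle miRNAs (miR-127-3p, miR-411-5p, miR-10a-5p, miR-199a-3p and miR-379-5p) all had lower fitted levels in LPS than in Control, with a median log2 fold change of -0.93. Their camera adjusted p was 0.699 and none passed singly. The 6 tested miRNAs of the list named myeloid-enriched, among them miR-191a-5p and miR-16-5p, all had higher fitted levels in LPS. Their median log2 fold change was 0.29 (camera adjusted p = 0.879). Whether these miRNAs mark myeloid cells was not tested. Among 9 LPS-induced miRNAs, which include miR-155-5p, miR-146a-5p, miR-21-5p and miR-222-3p, 5 were higher and 4 lower (camera adjusted p = 0.910). The inflammation-restraining list had 3 of 5 higher (adjusted p = 0.898), the pro-fibrotic list 2 of 5 higher (0.879), and the anti-fibrotic list, which holds miR-204-5p, 2 of 5 higher (0.998). The miR-17-92 list had 2 of 3 higher, the lymphocyte list 2 of 3 higher and the neural and endocrine list 1 of 4 higher, each with a camera adjusted p of 0.879. In the let-7 family 3 of 9 were higher, 1 passed over all miRNAs and 1 passed adjusted over the list alone, in both cases let-7a-5p. No member of another list passed over all miRNAs, and 0 passed adjusted over the list alone. Among the same members, summing tags of 0 or 1 mismatch gave 8 of 9 LPS-induced miRNAs higher, 4 of 5 pro-fibrotic, 5 of 9 let-7, 3 of 5 anti-fibrotic, 3 of 3 miR-17-92 and 5 of 6 myeloid-enriched miRNAs, and no list passed (smallest camera adjusted p = 0.543). That setting brought further miRNAs into the test, of which miR-17-5p, chosen after its values were seen, was lower and passed adjusted over the list alone in the miR-17-92 list (edgeR adjusted p = 0.0457), but not over all miRNAs (0.519). The let-7 median was -0.04 and its mean 1.58 while camera gave an upward direction (adjusted p = 0.879), and with DESeq2 size factors 4 rather than 6 of its members were lower.

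No list passed in any of the 3 comparisons by camera, where the smallest adjusted p was 0.699, and no list passed with an estimated correlation, where it was 0.954. fry, which tests whether a list's miRNAs move on balance in 1 direction and does not compare them with other miRNAs, called the let-7 family in both comparisons against Control (adjusted p = 0.00452 each). With each tag given to 1 miRNA, fry called 0 lists, with a smallest adjusted p of 0.172. Mean, median and test also differed in sign for the LPS-induced, inflammation-restraining, pro-fibrotic and anti-fibrotic lists in LPS against Control. The same held for the pro-fibrotic and the neural and endocrine lists in LPS+AS-IV against LPS, and for the inflammation-restraining and miR-17-92 lists in LPS+AS-IV against Control. Members with 0 reads in 1 group, set at their bound, left every list median as it was.

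The lists with under 3 tested members had no set test. For the miR-30 family, miR-30d-5p stood at 1220 ± 591 CPM in Control and 817 ± 756 CPM in LPS (SD, n = 3 each). Its share of the reads in the miRNA table was 0.128% ± 0.0611, 0.0787% ± 0.0757 and 0.462% ± 0.572 in Control, LPS and LPS+AS-IV (SD, n = 3 each). miR-30b-5p, described above, had 15, 1 and 1 reads in LPS+AS-IV. Of the erythroid list, miR-451-5p stood at 34891 ± 6681, 30727 ± 2561 and 31088 ± 7152 CPM in Control, LPS and LPS+AS-IV, and miR-486 at 8143 ± 1920, 1041 ± 1686 and 3796 ± 4936 CPM (SD, n = 3 each). Epithelial miR-429 and miR-375-3p had group means of at most 468 CPM. The endothelial list was represented by miR-126a-3p, the liver and serum list by miR-122-5p and miR-192-5p, and the family of miR-204 and miR-211 by miR-204-5p. None of their tests passed by edgeR. No striated muscle miRNA had enough reads to be tested.

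LPS+AS-IV against LPS asks whether astragaloside IV altered the exosomal response to LPS. miR-126a-3p stood at 8121 ± 4262 CPM in LPS+AS-IV and 3408 ± 1869 CPM in LPS, and miR-181b-5p at 19313 ± 7674 CPM and 9298 ± 5073 CPM (SD, n = 3 each). miR-222-3p stood at 6313 ± 2510 CPM in LPS+AS-IV and 12082 ± 2702 CPM in LPS (SD, n = 3 each). miR-532-3p and miR-1306-5p had no reads in LPS+AS-IV and were at least 11.7-fold and 2.68-fold lower than in LPS. The miR-532-3p bound was 6.997-fold without LPS 2, and miR-1306-5p had reads in LPS 1 alone (20), so no fold was left without it. Without LPS+AS-IV 1, which has the highest floor, the bounds were 40.4-fold and 9.28-fold. miR-128-3p was at least 10.6-fold higher and miR-125a-5p at least 4.70-fold higher on average than the LPS floor, each from reads in 1 library (1102 in LPS+AS-IV 3 and 64 in LPS+AS-IV 2). With 0 or 1 mismatch the log2 fold change was -0.63 (SE 2.995) for miR-532-3p, -1.59 (SE 2.59) for miR-1306-5p, 3.22 (SE 2.62) for miR-128-3p and 0.06 (SE 1.09) for miR-125a-5p.

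edgeR called 0 of 94 miRNAs higher and 0 lower, with 1 and 2 at an unadjusted p under 0.05. miR-3596a had the smallest adjusted p (log2 fold change -5.24, SE 1.35, adjusted p = 0.160), and all miRNAs named above had an adjusted p of 0.963. DESeq2 called 2, miR-128-3p and miR-3596a. Without LPS 1 edgeR called 1, miR-3596a. The log2 fold change of miR-3596a was -2.04 (SE 2.15, edgeR adjusted p = 0.980) with each tag given to 1 miRNA, and with 0 or 1 mismatch -1.08 (SE 0.42). In the lists, 8 of 9 let-7 miRNAs, 5 of 6 myeloid-enriched, 6 of 9 LPS-induced and 4 of 5 mesenchymal miRNAs had higher fitted levels in LPS+AS-IV, each with a camera adjusted p of 0.879. With DESeq2 size factors or library totals, 2 rather than 1 of the let-7 and of the myeloid-enriched miRNAs were lower. In the neural and endocrine list 3 rather than 2 of 4 were then lower. The majority turned with 0 or 1 mismatch for the LPS-induced list, with 4 of 9 higher, and for the myeloid-enriched list, with 2 of 6 higher, while the let-7 list had 7 of 9 and the mesenchymal list 4 of 5 higher (smallest camera adjusted p = 0.692). The inflammation-restraining list had 1 of 5 higher, the pro-fibrotic list 3 of 5, the anti-fibrotic list 3 of 5, the miR-17-92 list 1 of 3, the lymphocyte list 2 of 3 and the neural and endocrine list 2 of 4. In the mismatch setting the pro-fibrotic list had 1 of 5 higher, the miR-17-92 list 0 of 3, the lymphocyte list 1 of 3 and the neural and endocrine list 1 of 4. In the deposited counts their camera adjusted p lay between 0.879 and 0.898. The count over all miRNAs and the count adjusted over the list alone were both 0 in each list by edgeR, where 3 miRNAs had an unadjusted p under 0.05 and DESeq2 called 2.

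LPS+AS-IV against Control asks what remained different after both treatments. miR-181b-5p, a miRNA of lymphoid and myeloid cells, stood at 19313 ± 7674 CPM in LPS+AS-IV and 4783 ± 1639 CPM in Control (SD, n = 3 each), higher in each LPS+AS-IV library than in each Control library. Its log2 fold change was 2.01 (SE 0.61), with an unadjusted p of 0.00534 and an edgeR adjusted p of 0.167 over all miRNAs. It passed adjusted over the list alone in the lymphocyte list (adjusted p = 0.0160 by edgeR), whose count over all miRNAs was 0. Its log2 fold change with 0 or 1 mismatch was 1.16 (SE 0.43, edgeR adjusted p = 0.994), and the smallest edgeR adjusted p over the lymphocyte list alone was 0.0543, so this call was lost. miR-127-3p stood at 1786 ± 1888 CPM in LPS+AS-IV and 9254 ± 2370 CPM in Control, and miR-92a-3p at 106280 ± 41573 CPM and 73455 ± 8881 CPM (SD, n = 3 each). miR-532-3p and miR-1306-5p, with no reads in LPS+AS-IV, were at least 5.26-fold and 4.77-fold lower than in Control. The Control reads of miR-532-3p were all in Control 3 (105), so no fold was left without it, and the miR-1306-5p bound was then 2.34-fold. Leaving out LPS+AS-IV 1 gave bounds of 18.2-fold and 16.5-fold. With 0 or 1 mismatch the log2 fold changes of miR-532-3p and miR-1306-5p were 0.66 (SE 2.997), in the other direction, and -1.94 (SE 2.62).

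Of 94 miRNAs, edgeR called let-7a-5p higher (log2 fold change 16.07, SE 0.56, adjusted p = 3.43e-10, at least 1348-fold against the floor) and miR-3596a lower (-10.38, SE 1.63, adjusted p = 0.000922). The Control reads of miR-3596a came mostly from the tag named let-7a-5p elsewhere, and with each tag given to 1 miRNA edgeR called 0, with 1 at an unadjusted p under 0.05. The let-7a-5p level was then 86310 ± 14498 CPM in LPS+AS-IV (SD, n = 3), with a log2 fold change of 0.15 (SE 0.26, edgeR adjusted p = 0.977). DESeq2 on the deposited counts also called 2. The let-7 list had 7 of 9 higher fitted levels and the mesenchymal list 3 of 5 lower, and the neural and endocrine list had 4 of 4 lower, each with a camera adjusted p of 0.699. The myeloid-enriched list had 6 of 6 higher, the LPS-induced list 6 of 9, the inflammation-restraining list 3 of 5, the anti-fibrotic list 4 of 5 and the lymphocyte list 3 of 3, each with a camera adjusted p of 0.879. With library totals the lymphocyte count turned to 2 of 3 lower and the pro-fibrotic count to 3 of 5 lower. With 0 or 1 mismatch 4 of 6 myeloid-enriched, 7 of 9 LPS-induced, 2 of 5 inflammation-restraining, 2 of 5 pro-fibrotic, 1 of 5 mesenchymal and 2 of 3 lymphocyte miRNAs were higher. The pro-fibrotic list had 3 of 5 higher (0.910) and the miR-17-92 list 2 of 3 (0.998). In the let-7 list 1 miRNA passed over all and 1 adjusted over the list alone. Apart from these and miR-181b-5p, no list member passed either count.

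Across the 94 miRNAs, the change of LPS+AS-IV against LPS correlated negatively with the change of LPS against Control (Pearson r = -0.441, Spearman rho = -0.439, covariance -3.19). Both changes share the LPS libraries, which gives a negative relation by chance, and miRNAs are not independent replicates. Without let-7a-5p and miR-3596a, r was -0.611, rho -0.488 and the covariance -3.55 over 92 miRNAs. In 100 simulations of unchanged groups the median r was -0.525, rho -0.455 and covariance -3.11, and 25 simulations had an r and 33 a covariance at or below the values without these names. The 3 LPS libraries could not be split into parts of at least 2 libraries, so part of the relation may come from them. Without LPS+AS-IV 2 the r over all miRNAs was -0.152.

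**Figure D4:**
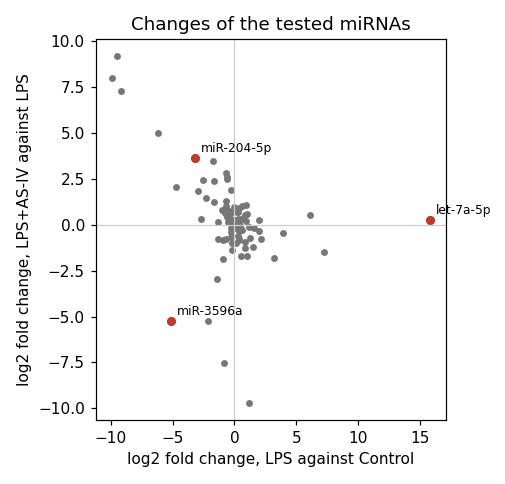
Fitted log2 fold change of LPS+AS-IV against LPS (vertical axis) over that of LPS against Control (horizontal axis) for the 94 tested miRNAs (points), with r = -0.441. Red points mark miR-204-5p, let-7a-5p and miR-3596a, and the farthest points are miRNAs with 0 reads in 1 group, whose fitted values are no bounds.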

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

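All tests in this part were chosen after the result they bear on was seen, with exceptions. These are the comparison with other splits of the libraries and the main edgeR test on the deposited counts. Reads assigned to rRNA and transfer-messenger RNA families of bacterial type were not part of the comparisons, and some libraries exceeded the highest Control share. Bacterial large-subunit rRNA families held 15.6% of assigned reads in LPS 1, 26.8% in LPS 2 and 18% in LPS+AS-IV 1, against 12.4% to 13.5% in Control. By family assignment they held 3.24% in LPS 3, 11.2% in LPS+AS-IV 2 and 8.67% in LPS+AS-IV 3, below each Control library. Transfer-messenger RNA families held 1.31% in LPS 2 and 2.26% in LPS+AS-IV 3, against 0.911% to 1.22% in Control. They held 0.566% in LPS 1, 0.733% in LPS 3, 0.540% in LPS+AS-IV 1 and 0.617% in LPS+AS-IV 2, below each Control library. Groups of 3 libraries were not tested for outliers.

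The bacterial-type reads could come from bacteria in the preparation or from the treatment. More reads carried a conserved core of bacterial large-subunit rRNA than the matching eukaryotic core in 7 of the 9 libraries, which is what RNA from bacteria would give. Reads with the bacterial core were also filed under the matching eukaryotic rRNA family. They made up 39.7% to 77.8% of that family in Control, 0.936% in LPS 3 and 77.3% in LPS+AS-IV 2. LPS+AS-IV 2 had 2467576 bacterial core reads, beside 1016526 in the bacterial large-subunit families. The family shares above therefore do not rank libraries by bacterial rRNA. The lowest ratio of bacterial to eukaryotic core reads in the Control libraries, which received DMSO only, was 8.07, so LPS or astragaloside IV is not needed for these reads. The ratio was 17.4, 34.3 and 0.0655 in LPS and 19.96, 12.3 and 0.876 in LPS+AS-IV, and whether treatment shifted it stayed open (exact permutation p of 1, 0.9 and 0.9). The origin of these reads was not tested further.

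let-7a-5p at 0 reads in Control, with miR-3596a high there, may come from 1 tag sequence given 2 names. With each tag given to 1 miRNA in every library, the largest absolute log2 fold change of let-7a-5p over the comparisons was 0.27, which this explanation needs. A treatment effect on let-7a-5p of the size in the deposited table is argued against by the same value, whose SE was 0.26, well below a log2 fold change of 1. The smallest adjusted p against Control was then 0.961. Why the assignment differed between libraries was not tested.

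miR-204-5p was lower in the LPS libraries than in all others, and the treatment named by the design and a low number of starting molecules were weighed. Loss of LPS reads to tags with 1 mismatch is argued against by the counts. With tags of 0 or 1 mismatch summed, miR-204-5p had 3, 1 and 24 reads in LPS, beside 3, 1 and 20 without a mismatch. The log2 fold change in LPS against Control was then -3.22, and it did not pass the test. Loss to tags of other kinds was not tested. In units of the modal tag count, rounded, miR-204-5p came to 2, 2 and 1 in Control, 0, 0 and 0 in LPS, and 0, 3 and 1 in LPS+AS-IV. Fisher's exact p of LPS against Control was 0.166 in these units. It was 0.0312 with 0.5 times the modal count as the unit and 0.54 with 2 times. For LPS+AS-IV against LPS, Fisher's exact p was 0.139, 0.0120 and 0.51 in the same order. These tests pool libraries and take the unit as 1 molecule, which stayed open. Their p changed with the unit, so they decide nothing about a low number of molecules. The edgeR adjusted p was 0.802, so the treatment effect also stayed open.

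Other splits of the 6 libraries compared were refitted by edgeR. In LPS against Control the real split called 1 miRNA and the highest other 0, so 1 of 10 splits gave as many. In LPS+AS-IV against LPS the real split called 0 and the highest other 1, so 10 of 10 gave as many. In LPS+AS-IV against Control the real split called 2 and the highest other 0, so 1 of 10 gave as many. With 10 splits, a share under 0.05 cannot be reached.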

How the results depend on the processing

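The tag assignment, mismatch, exp column, modal count and 2-library alternatives, the block with tags by sequence, and the relation without let-7a-5p and miR-3596a were chosen after the data were seen. Over 3162 alternative values of 162 results of named miRNAs, 3131 kept their direction where called and their side of the threshold, 5 lost and 22 gained the threshold, and 4 reversed. Signs of uncalled values changed 312 times, in 88 results. In LPS against Control, where the count was 1, it was 2 with library totals, no filter, the 3 most abundant miRNAs left out or the exp column. It was 3 with DESeq2 or with only the 6 libraries compared, 4 with modal count units and 0 with tags by sequence or with 0 or 1 mismatch, and 1 to 3 with a replicate left out. In LPS+AS-IV against LPS, the count of 0 became 1 without a filter and 2 with DESeq2, and 0 to 1 with a replicate left out. In LPS+AS-IV against Control, the count of 2 became 0 with tags by sequence or with 0 or 1 mismatch and 4 with modal count units, and it was 2 to 3 with a replicate left out. Giving each tag 1 name ended these calls because 1 tag was named miR-3596a in Control and let-7a-5p elsewhere. The mismatch setting also gave each tag 1 name, so its counts of 0 are not a separate check. The miR-652-3p calls without Control 1 also rested on naming, since its tags were named a piRNA in Control 2 and Control 3. For the rest the cause was not tested. let-7a-5p in LPS against Control reversed to -0.13 by sequence and -0.12 by sequence with the block, and miR-3596a in LPS+AS-IV against Control to 0.48 and 2.62. Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated between 0.103 and 0.149 for number 1 but between -0.122 and 0.012 for the others, and 3 of 9 libraries correlated best with their own number. With a replicate block the counts were 2, 1 and 2, and by sequence with the replicate block 1 (miR-486), 0 and 0. Calls added were miR-3596a, miR-128-3p (DESeq2), miR-127-3p (6 libraries, modal units), miR-486 and miR-181b-5p (modal units) and miR-652-3p (without Control 1). Without the 2 libraries with fewer bacterial than eukaryotic core reads, the counts were 1, 0 and 2. miR-204-5p stayed short of the threshold in 20 settings, between -4.47 and -2.53 (adjusted p 0.166 to 0.992), 2.80 and 4.92 (0.0764 to 1), and -0.00 and 0.60 (0.942 to 1) in the 3 comparisons. fry called 1 list in each comparison against Control, and the other list settings called 0, as camera did. The r of -0.441 moved to -0.620 by sequence, -0.788 with 0 or 1 mismatch, -0.655 by sequence with the replicate block and -0.611 without both names, and lay between -0.654 and -0.152 with a replicate left out. Class shares changed sign in 17 of 96 alternatives, and their tests could not pass at this size. Other pseudocounts were not run, since the values were counts. Of the 94 miRNAs, 50 had 0 reads in at least 1 library, and a count of 0 allowed up to 3 reads, or 5.99 to 216 CPM by library.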

Other observations

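The tests in this part were chosen after the data were seen. Of the 94 tested miRNAs, 1 (miR-204-5p) had all 3 LPS libraries below the 6 others, and 1 (miR-222-3p) had all 3 above them. With each tag given to 1 miRNA, 1 (miR-204-5p) was lowest and 2 (miR-222-3p and miR-3596a) highest. In LPS this miR-3596a was the let-7a-5p tag with 1 base added, which the deposited files named let-7a-5p in some libraries. It is therefore not shown to be a miRNA distinct from let-7a-5p. With tags of 0 or 1 mismatch, 5 of 129 (miR-1249, miR-17-5p, miR-204-5p, miR-26b-5p and miR-342-5p) were lowest and 2 (miR-222-3p and miR-3596a) highest. Of these, miR-1249, miR-17-5p, miR-26b-5p and miR-342-5p lay outside the naming rule and were chosen after their values were seen. Chance gives a single miRNA 1.19% per direction for any fixed group of 3 among 9 libraries, which is the value for miR-204-5p, named in the series title. Whether the study chose it on these libraries is not given in the sources used here. Over all miRNAs chance gives 1.12 of 94 and 1.54 of 129, and whether 5 exceeds this was not tested.

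miR-21-5p, abundant in many cells, had few reads in tags scored with 0 mismatches. Its reads in these tags were 120, 83 and 231 in Control, 5, 4 and 298 in LPS, and 21, 428 and 493 in LPS+AS-IV. With tags of 0 or 1 mismatch it had 2716, 1509 and 4020, 1346, 1971 and 4647, and 705, 4319 and 9166 reads. Its log2 fold change in LPS against Control was then 0.11 (SE 0.40, edgeR adjusted p = 0.979), beside -0.70 (SE 1.49) in the deposited table.

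A hypothesis for the peaks in log-binned reads per tag is that a tag at the modal count may stem from 1 amplified starting molecule. Such tags should then often be missing from other libraries of the group, but differences between samples also remove tags. The median share of them with at most 3 reads in another library of the group was 80.7% (range 72.9% to 94.9% over 18 library pairs). For miRNA tags the median was 54.4% (17.5% to 77.3%). These values do not separate the 2, the hypothesis was formed on the same data, and it stayed open, since molecules were not counted directly.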
